A study of Bos taurus with 4 samples.

How the data were processed

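RNA from bovine blastocysts sired by bulls aged 10 or 16 months was compared on 4 two-channel oligonucleotide arrays, each of which held 1 sample of either age. Per the labels' protocols, RNA was extracted with a combined DNA and RNA kit, amplified with a commercial kit, and tagged chemically with Cy3 or Cy5 at guanine bases. The 10-month sample carried Cy5 on replicates 1 and 2 and Cy3 on replicates 3 and 4, so that each dye orientation had 2 arrays. The scanner and its quantification software are not given in the sources used here.

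Per the file headers, the deposited scan files gave, for each of 45220 spots, the foreground and local background intensity at 635 nm (Cy5) and 532 nm (Cy3) on a linear scale. They also marked spots that the scan software had set aside (39, 21, 34 and 82 on replicates 1 to 4). These intensities had not been normalised. The authors' deposited value table of the same arrays held log2 ratios, made with limma per the submitters' processing notes, whose version is not given in the sources used here. Its background correction and filters are likewise not given. Each column correlated with the loess-normalised log2 Cy5 over Cy3 ratio of its own array at r = 0.991, 0.978, 0.978 and 0.980, so the table ran Cy5 over Cy3 on all 4 arrays. Column medians were -0.02, -0.01, -0.01 and -0.01. Whether those medians were set on purpose remained unknown. The table served as an alternative.

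Ratios were computed in R 4.3.3 with limma 3.58.1. Spot medians were corrected with normexp on the local background (offset 50), leaving out set-aside spots, and normalised within each array by loess, with weight 0 for control spots. A probe counted as above background where its spot median exceeded the median of the negative control probe by more than 2 median absolute deviations. Probes above background in either channel on at least 2 arrays were tested. Of 43794 embryo probes, 175 were left out because a spot was set aside on any array and 7294 because they were dim, which left 36325. Sensitivity of an array is limited by this background, and the number of arrays limits the precision.

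Some of these choices were made after the data had been seen, with the age test in view each time. Spot means with all spots in the background fit were used first, then spot medians with all spots, then spot medians without the set-aside spots. The detection threshold was also changed on the way, from a mean and SD to a median and median absolute deviation. The reasons were technical. Ratios from spot medians correlated with the authors' table at 0.978 to 0.991, though no such value for spot means is given here. A few set-aside spots with strongly negative net signal pulled the fitted Cy3 background mean of replicates 1 and 4 to -217 and -298, against 143 and 135 without them. Recomputed with the final threshold, no probe passed the adjusted test under any of the 3 (limma, 902, 806 and 1439 probes at an unadjusted p under 0.05). The count of probes past an unadjusted p of 0.05 and a 1.5-fold difference was 2, 30 and 58 in that order, so the version kept gave the highest count. The gene lists called were 2, 4 and 3 in that order.

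The comparison used lmFit and eBayes on the log2 ratio, with a dye coefficient and an age coefficient of +1 or -1, fixed before the data were examined. Log2 ratios are given as 10 over 16 months, with the standard error of the fit over the 4 arrays. Its variance borrows from other probes and leaves the dye effect out, so it is not the SD of the 4 values. Values and list medians given for single arrays still hold the dye effect. The fit has 2 residual degrees of freedom and gained 5.72 from the prior over probes. P-values were adjusted by Benjamini-Hochberg over all tested probes, with a threshold of 0.05. The labels number the arrays as biological replicates without tying each to a bull. The p-values therefore measure only the spread between these arrays, combined with the prior over probes, and not a spread between bulls. All 4 arrays lay on 1 slide, so no slide batch existed to test.

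Gene symbols came from the platform annotation and can be old. It gave 1 symbol to 21790 probes, several to 0 and none to 22004. Of 15229 distinct symbols, 15190 matched a current symbol or synonym in a RefSeq table for assembly ARS-UCD2.0, which was used for names only. The 18710 tested probes with a symbol stood for 13504 genes, each represented by its brightest probe. No coordinates are given, since the build behind the probes is not given in the sources used here.

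Before the data were examined, 29 gene lists were written, covering embryonic lineages, metabolism, stress, translation, chromatin, imprinting, sex chromosomes and other cells that embryo pools could carry. Each list with at least 5 measured genes was tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and fry as alternatives. Genes are named by a rule fixed in advance. Per direction it takes up to 10 genes past the adjusted test and of the same sign on all 4 arrays, filled up by smallest unadjusted p among genes of the same sign on all 4 arrays with at least a 1.5-fold difference. Per list it takes members past 0.05 adjusted over the list alone or else the 2 members of smallest p, and it adds a fixed set of lineage, imprinted, methylation, sex-linked, germline and reference genes. Of that set, GATA6, H19 and GAPDH had no probe with that symbol, and IGF2 and GDF9 had only dim probes. Further genes named below were chosen after their values were seen, as stated there.

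The fit was tested on simulated data with the 36325 probes and the spread of these arrays. It recovered 3 of 50 probes changed by 1.5-fold, 36 of 50 changed by 2-fold, and all 50 at 4-fold and at 8-fold, with 1 false call. All changed probes were in 1 fit, so the larger changes eased the adjusted threshold for the smaller ones. Recovery with fewer changed probes was not simulated. The list test called both of 2 lists shifted by 0.3 on the log2 scale and 0 of 26 others. Simulated genes varied independently, with the same noise on all 4 arrays. That 0 therefore does not bear on lists whose genes vary together. The largest list median found below, for oxidative phosphorylation, was smaller in size than this shift, at -0.15. Alternatives varied the dye term, background correction, normalisation, probe filter, array weights, variance model, list test, probe choice and the pairing of channels, and left out each array in turn. A scanner-processed signal was not analysed here.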

Results

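Blastocysts are embryos that have formed an outer trophectoderm, which gives rise to the placenta, and an inner cell mass, which gives rise to the fetus. Those measured here were produced in vitro from slaughterhouse oocytes and sperm of young bulls, and the study compared sires at 10 and at 16 months, around puberty. The design names 4 bulls, each collected at both ages. Each of the 4 arrays held embryos of both ages in opposite dyes, with 2 arrays per dye orientation. Of 43794 embryo probes, 35972, 34676, 34628 and 33452 were above background in either channel on replicates 1 to 4. The SD of the log2 Cy5 over Cy3 ratio over probes was 0.32, 0.30, 0.47 and 0.32, so replicate 3 was the widest. The 29 control probes printed 10 times had a median SD between spots of 0.28 on that array, against 0.21, 0.18 and 0.21 on replicates 1, 2 and 4. These were mostly RC, ETG and eQC controls, with Cy5 medians of 102.5, 106.5 and 122 on replicate 3, against 103 for the negative control. The SD therefore describes spots near background.

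Among genes with the same sign on all 4 arrays and at least a 1.5-fold difference, those of smallest unadjusted p in each direction were PROCR, LINGO1 and IL1A, with higher values in embryos sired at 10 months, and HIST1H2BN and ID3, with lower values, but none passed the adjusted test. The genes named here and below come from the version kept. With spot means and all spots kept, the first version tried, 0 probes with higher values met both an unadjusted limma p under 0.05 and a 1.5-fold difference. PROCR, the endothelial protein C receptor, had a log2 ratio of 0.70 ± 0.12 (SE, 4 arrays), which is 1.63-fold. LINGO1, a leucine-rich repeat membrane protein known from neurons, was at 0.92 ± 0.17, and the cytokine interleukin 1 alpha (IL1A) at 0.82 ± 0.18. ID3, an inhibitor of basic helix-loop-helix transcription factors and a target of BMP signalling, was at -0.91 ± 0.26, with -2.17 on replicate 2 and -0.49 as the fitted value without it, and the histone gene HIST1H2BN at -0.75 ± 0.16. These values use the recorded dye orientation of replicate 3. With its sign turned they were 0.42 for PROCR, 0.36 for LINGO1, 0.54 for IL1A, -0.38 for ID3 and -0.77 for HIST1H2BN. That fit sets 3 arrays against replicate 4 alone and gives replicate 4 more weight. The turned values therefore mix orientation with weight.

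With limma, 0 of 36325 probes passed the adjusted threshold for sire age, and the smallest adjusted p was 0.957. At an unadjusted p under 0.05 there were 1439 probes (3.96%), of which 743 were higher and 696 lower at 10 months, where chance alone gives 1816. A 1.5-fold difference as well was met by 58 probes, 46 higher and 12 lower, and these held 23 named genes. With the sign of replicate 3 turned it was met by 135 probes, 108 higher and 27 lower, of which 5 were among the 58. With median centring in place of loess that split was 30 higher and 18 lower, with the authors' value table it was 27 and 13, and with spot means and all spots kept, the first version tried, it was 0 and 2. All 4 arrays had the same sign at 9.37% of probes. Independent arrays without a dye effect would give 12.5% by chance, but these ratios followed the dye in part, so that share is no exact reference. The 95% interval of the log2 ratio reached a median of 0.30 to either side, a 1.23-fold difference, and excluded a 2-fold difference in the computed ratio at 99.4% of probes. The offset of 50 added to both channels shrinks the ratios of dim probes, and the simulated changes were set after it. On replicate 1 the median Cy5 signal of probes was 122, against 80 for the negative control. A 2-fold difference in RNA was therefore not excluded at dim probes. Changes of 1.5-fold were mostly not detectable with these arrays, as 3 of 50 simulated ones were recovered. The adjusted count rested on which arrays were used: it was 6 without replicate 3 and 1858 without replicate 4, a fit in which replicate 3 is the lone array of its dye orientation.

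**Figure D1:**
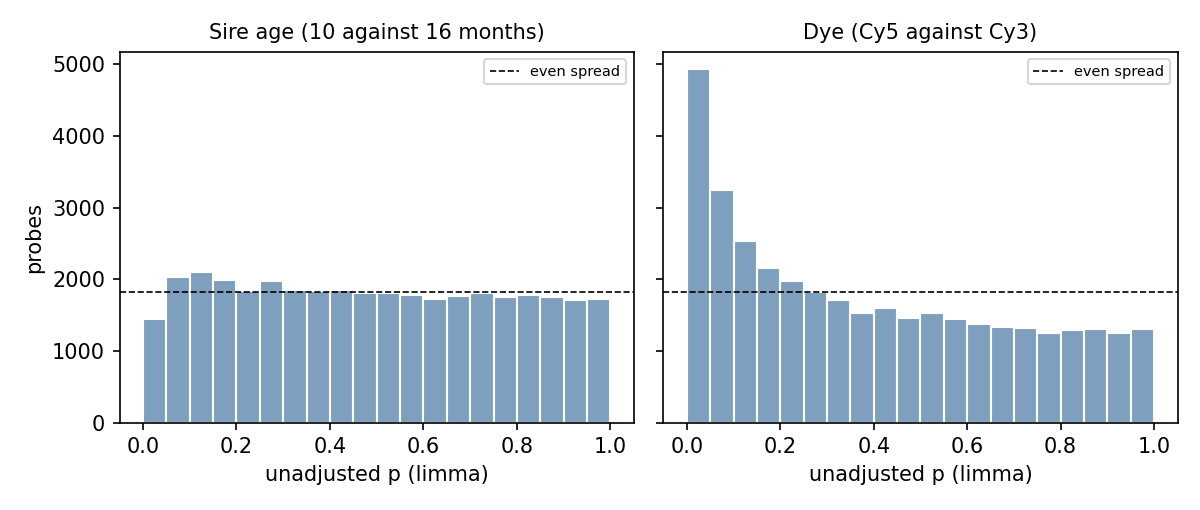
Number of probes (vertical axis) per unadjusted limma p-value bin of width 0.05 (horizontal axis) for sire age (left) and for dye (right), with a dashed line at an even spread. The lowest bin holds 1439 probes for age and 4930 for dye.

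The other genes that the naming rule took as higher at 10 months, none past the adjusted test, were EPAS1, SENP2, ZMYND17, LOC781710, C1H21ORF2, KIF27 and HOXC4. EPAS1, the hypoxia-inducible factor 2 alpha, was at 0.73 ± 0.21 and the SUMO protease SENP2 at 0.73 ± 0.22. Both rested on replicate 3, with values of 1.90 and 1.82 there and at most 0.48 and 0.38 on the other arrays, and the fitted values without it were 0.38 and 0.36. ZMYND17, now MSS51, was at 0.70 ± 0.17 and the homeobox gene HOXC4 at 0.61 ± 0.16. LOC781710 was at 0.65 ± 0.15, C1H21ORF2 (now CFAP410) at 0.62 ± 0.15 and the kinesin KIF27 at 0.62 ± 0.18. The retinoid-binding protein gene RLBP1 completed the lower genes at -0.60 ± 0.18. Without replicate 3, KIF27 was at 0.34 and RLBP1 at -0.33, and with its sign turned the values of EPAS1, SENP2, KIF27 and RLBP1 were 0.018, 0.00096, 0.039 and -0.040. Other probes of LINGO1, ID3 and C1H21ORF2 disagreed in part: over all probes of each gene, the mean log2 ratio was 0.21 for LINGO1, -0.22 for ID3 and 0.14 for C1H21ORF2. Without replicate 4, where replicate 3 stands alone for its dye orientation, all 13 genes taken by the rule passed, with adjusted p from 0.0108 (LINGO1) to 0.0415 (C1H21ORF2).

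**Figure D2:**
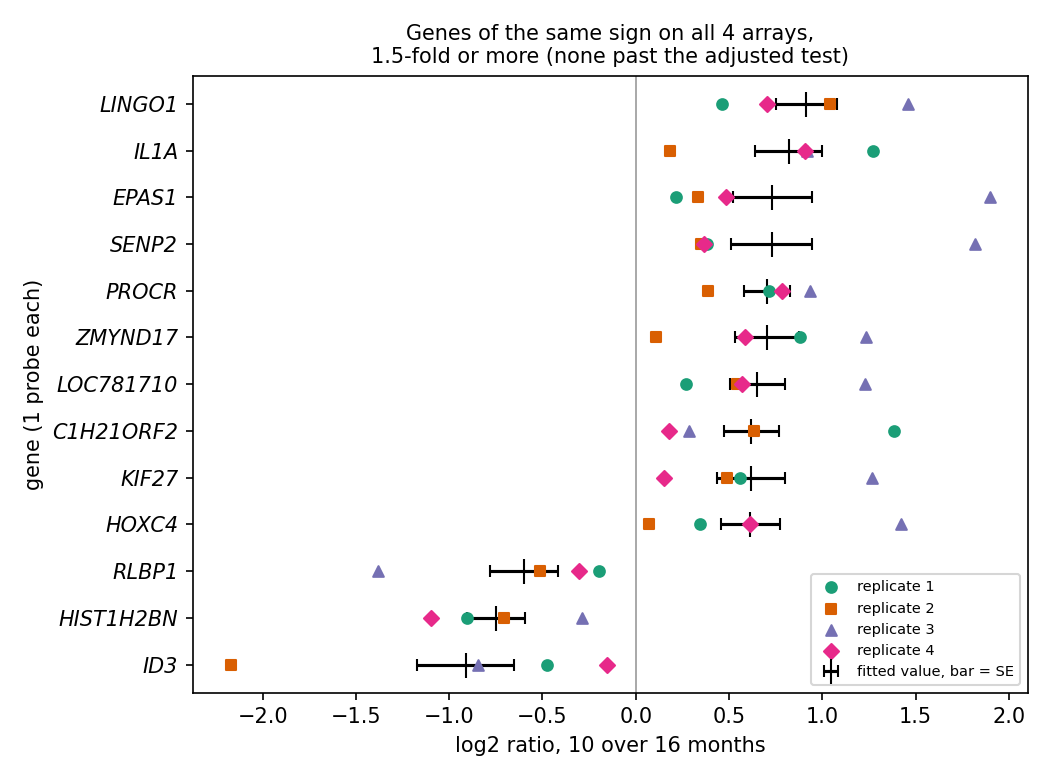
Log2 ratio of 10 over 16 months (horizontal axis) for the 13 genes of the same sign on all 4 arrays that the naming rule took (vertical axis), with 1 symbol per replicate and the fitted value with its SE as a black bar. The symbols of EPAS1 and SENP2 on replicate 3 lie at 1.90 and 1.82, apart from the other 3.

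Embryonic lineage genes did not pass the test. Among 22 trophectoderm genes measured, 0 passed, the median was -0.10 (camera adjusted p = 0.230), HAND1 was at -0.28 ± 0.12 and ASCL2 at 0.31 ± 0.15. CDX2 and GATA3, which specify trophectoderm, were at -0.01 ± 0.12 and -0.18 ± 0.12. Among 19 inner cell mass genes 0 passed and the median was 0.07 (adjusted p = 0.170), with NANOG at 0.30 ± 0.14 (0.17 without replicate 3) and STAT3 at 0.29 ± 0.12 (mean over its 3 probes 0.0088). POU5F1 was at -0.16 ± 0.16 and SOX2 at 0.15 ± 0.16. Among 20 primitive endoderm genes 0 passed and the median was -0.04 (adjusted p = 0.183), with the basement membrane genes LAMA1 at -0.47 ± 0.15 and COL4A1 at -0.35 ± 0.14. LAMA1 was at -1.26, -0.90, 0.48 and -0.20 on replicates 1 to 4, values that still hold a dye effect fitted at -0.61 (log2 Cy5 over Cy3). Its fitted value without replicate 4 was -0.30. Of 11 secreted trophoblast products, 0 passed and the median was -0.07 (adjusted p = 0.579). Interferon tau (IFNT), the pregnancy recognition signal of ruminants, was at 0.04 ± 0.36, with -1.94 on replicate 3 and 0.60 to 0.76 on the others. TKDP1 was at 0.65 ± 0.31, with 2.27 on replicate 4, and PAG20 at -0.21 ± 0.13.

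Oxidative phosphorylation, ribosomal protein and translation genes were the 3 lists of 28 called with camera at the preset correlation, all toward lower values at 10 months. The 74 nuclear genes of oxidative phosphorylation had a median log2 ratio of -0.15 (adjusted p = 1.54e-09), and 68 were negative. With the correlation estimated, at 0.158 in place of 0.01, the camera adjusted p was 0.619. The median was -0.24, -0.13, -0.25 and 0.04 on replicates 1 to 4. Without replicate 3 it was -0.081 (adjusted p = 0.00104). With the sign of replicate 3 turned it was -0.0021. That fit sets replicate 4 alone against 3 arrays and gives it more weight. It therefore does not show how far the list median rests on the recorded dye orientation. None of the list's members passed, over all probes or over the list alone. An unadjusted p under 0.05 was found for 5, among them the succinate dehydrogenase subunit SDHC at -0.38 ± 0.13 and cytochrome c1 (CYC1) at -0.33 ± 0.12 (mean over its 2 probes -0.11).

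The 64 ribosomal protein genes had a median of -0.13 (adjusted p = 7.36e-07, and adjusted p = 0.619 with an estimated correlation of 0.183), and 53 were negative. That list went both ways between arrays, at 0.20, -0.09, -0.50 and -0.28 on replicates 1 to 4, and its median was -0.069 without replicate 2 (adjusted p = 0.0556) and -0.19 without replicate 1. With the sign of replicate 3 turned it was -0.084 (adjusted p = 0.235). RPS3A was at -0.57 ± 0.12 and RPS15A at -0.41 ± 0.12 (mean over its 3 probes -0.16), and no member passed over the list alone. The 49 genes of translation factors and mTOR signalling had a median of -0.075 (adjusted p = 0.0321, and adjusted p = 0.619 with an estimated correlation). The median was negative on 4 of 4 arrays as recorded and was -0.075 with the sign of replicate 3 turned (adjusted p = 0.500), with EEF1A1 at -0.39 ± 0.13 and TSC2 at -0.34 ± 0.13, and no member passed. The translation call was lost without replicate 1, 3 or 4 (medians -0.074, -0.072 and -0.13, adjusted p = 0.125, 0.101 and 0.180), with median centring (adjusted p = 0.0625), and with spot means and all spots kept (adjusted p = 0.0792). Over all 28 lists, fry called 0 in 1 direction, with a smallest adjusted p of 0.0936, and 0 in either direction, and camera with an estimated correlation called 0.

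**Figure D3:**
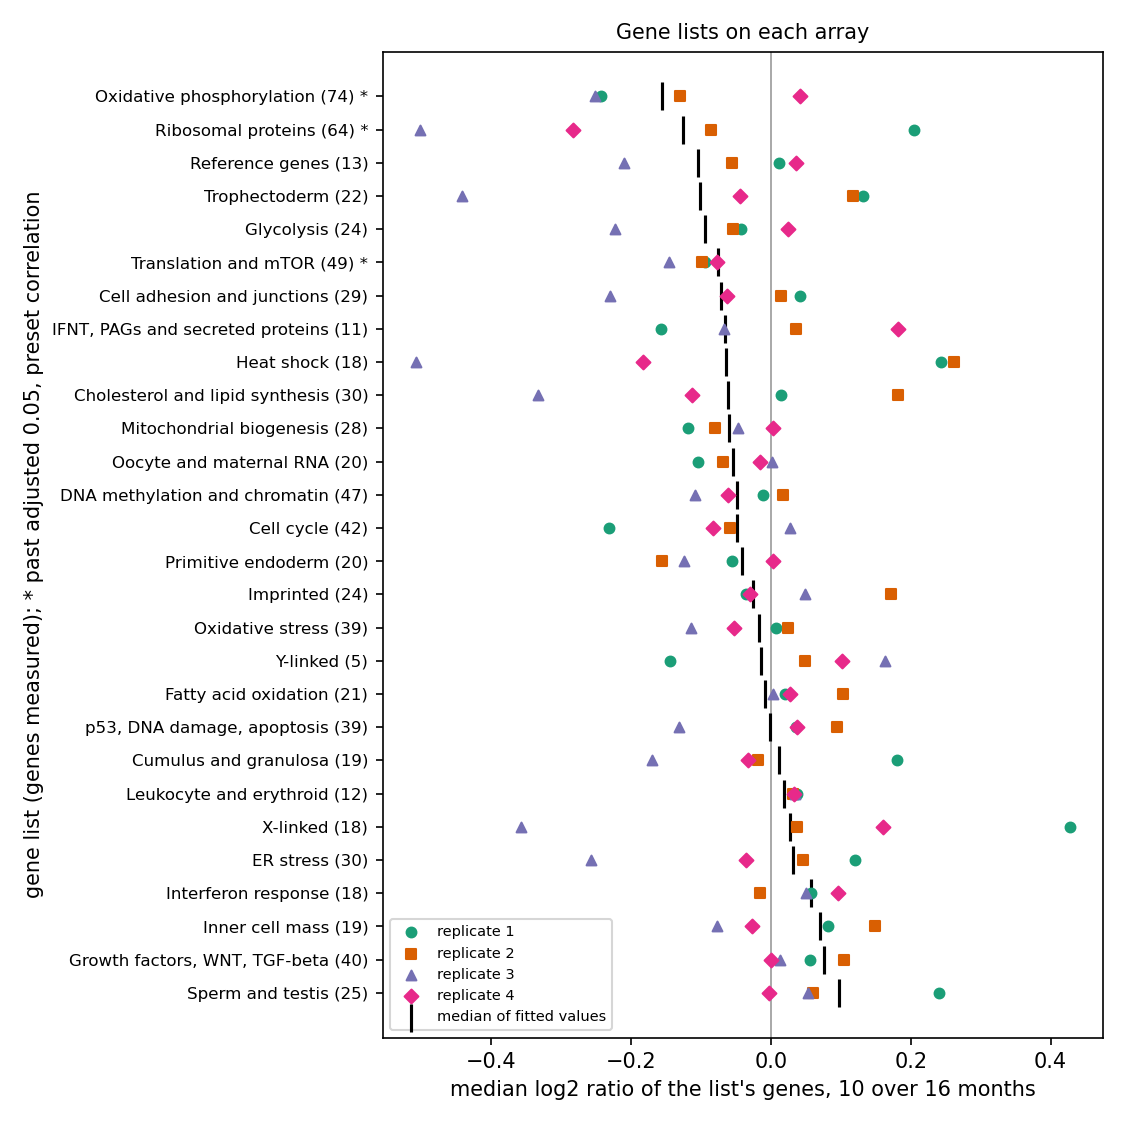
Median log2 ratio of 10 over 16 months (horizontal axis) of each of 28 gene lists (vertical axis, genes measured in brackets), with 1 symbol per replicate and a black bar for the median of the fitted values; an asterisk marks the 3 lists past the adjusted threshold at the preset correlation. Ribosomal proteins lie at 0.20 on replicate 1 and at -0.50 on replicate 3.

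Other metabolic lists did not pass with all 4 arrays. The median was -0.06 over 28 genes of mitochondrial biogenesis (adjusted p = 0.319), with LONP1 at 0.36 ± 0.18 and TFAM at -0.22 ± 0.12. It was -0.09 over 24 glycolysis genes (adjusted p = 0.183), with PGD at -0.41 ± 0.12 and ALDOA at -0.35 ± 0.17. It was -0.0088 over 21 fatty acid oxidation genes (adjusted p = 0.973), with CPT1B at -0.27 ± 0.15 and CPT1A at 0.17 ± 0.12. It was -0.06 over 30 genes of cholesterol and lipid synthesis (adjusted p = 0.148, and 0.0247 without replicate 2), with INSIG1 at -0.30 ± 0.14 (mean over its 3 probes 0.036) and SREBF2 at 0.44 ± 0.22 (mean over its 3 probes 0.088). Of 13 genes encoded by mitochondrial DNA, 0 were measured under their symbols.

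Stress and growth lists did not pass in the main setting either. The median was -0.02 over 39 oxidative stress genes (adjusted p = 0.736), with sulfiredoxin (SRXN1) at 0.42 ± 0.12 (mean over its 2 probes 0.22) and superoxide dismutase SOD1 at 0.31 ± 0.13 (mean over its 2 probes 0.21). Over 30 genes of endoplasmic reticulum stress it was 0.03 (adjusted p = 0.540; -0.03 with median centring), with MANF at 0.26 ± 0.12 and ATF3 at 0.27 ± 0.13. Over 18 heat shock genes it was -0.06 (adjusted p = 0.691), with HSPA1B at 0.36 ± 0.14 and HSPA4 at -0.32 ± 0.13. Over 39 genes of p53, DNA damage and apoptosis it was -0.0019 (adjusted p = 0.897), with CASP9 at 0.28 ± 0.12 (mean over its 3 probes 0.10) and BCL2L1 at -0.28 ± 0.13 (mean over its 3 probes -0.040). Over 42 cell cycle genes it was -0.05 (adjusted p = 0.132, and 0.0243 without replicate 2 and 0.00339 without replicate 3), with RRM2 at -0.35 ± 0.15 (mean over its 3 probes -0.20, and -0.17 without replicate 1) and MCM5 at -0.32 ± 0.14 (-0.20 without replicate 1). Over 18 interferon response genes it was 0.06 (adjusted p = 0.403), with IFIT5 at 0.48 ± 0.11 and USP18 at 0.19 ± 0.12 (mean over its 2 probes 0.075). That USP18 probe was above background on 3 arrays at 10 months and on 0 at 16 months, and the other USP18 probe on 1 and 3. Over 29 adhesion and junction genes it was -0.07 (adjusted p = 0.147), with F11R at -0.40 ± 0.12 and TJP3 at 0.57 ± 0.18. Over 40 growth factor, WNT and TGF-beta genes it was 0.08 (adjusted p = 0.156, and 0.0452 with a stricter filter), with NOTCH2 at 0.40 ± 0.13.

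Epigenetic and imprinted genes were examined because sperm carry epigenetic marks into the embryo. None of 47 genes of DNA methylation and chromatin passed, and their median was -0.05 (adjusted p = 0.210). The methyltransferases DNMT1, DNMT3A and DNMT3B were at -0.06 ± 0.22, -0.26 ± 0.12 and -0.16 ± 0.13, and the mean over the 3 probes of DNMT3A was -0.13. TET3, which oxidises methylcytosine in the zygote, was at 0.45 ± 0.20, with 1.52 on replicate 3 and 0.12 as the fitted value without it. Without replicate 4 TET3 was at 0.77 (adjusted p = 0.0139). None of 24 imprinted genes passed, with a median of -0.03 (adjusted p = 0.973), GNAS at -0.42 ± 0.13 (mean over its 3 probes -0.18), IGF2R at 0.23 ± 0.20, PEG3 at -0.07 ± 0.14 and SNRPN at -0.07 ± 0.13 (mean over its 3 probes 0.012).

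Lists of markers of other cells and of embryo sex did not pass in the main setting, though other settings called some of them. In the oocyte and maternal RNA list (20 genes, median -0.05, adjusted p = 0.210), BTG4, which triggers decay of maternal mRNA, was at -0.82 ± 0.16. Its adjusted p was 0.0203 adjusted over the list alone and 0.957 over all probes. It was the only member of any list to pass over its list alone. BTG4 had a fitted dye effect of -0.76 (log2 Cy5 over Cy3), which its values on single arrays still hold. Its values were -1.23, -1.92, 0.22 and -0.34 on replicates 1 to 4, and the call over the list alone was lost without replicate 2 (adjusted p = 0.220). It was also lost with no background correction, a trended robust variance, no dye term, separate channels, spot means, set-aside spots kept, or both of these (adjusted p from 0.0533 to 0.689). The stricter filter, which asked for signal above background in both channels on all 4 arrays, left the BTG4 probe out. BTG4 stayed at -0.82 with the variance model, the dye term or the channels changed, and was at -0.71 with no background correction, -0.58 with spot means, -0.56 with set-aside spots kept and -0.46 with both. It was at -0.65 without replicate 2. The cumulus and granulosa list (19 genes) had a median of 0.01 (adjusted p = 0.973), with VCAN at -0.16 ± 0.11 and INHBA at 0.18 ± 0.15. The leukocyte and erythroid list (12 genes) had a median of 0.02 (adjusted p = 0.654), with CD74 at -0.29 ± 0.12 and PTPRC at 0.49 ± 0.20. The sperm and testis list (25 genes) had a median of 0.10 (adjusted p = 0.0806, but 0.0215 with median centring, 0.0170 with no filter and 0.00688 without replicate 2), with SPATA6 at 0.58 ± 0.18 (0.31 without replicate 1), CATSPER3 at -0.23 ± 0.14 and protamine PRM1 at 0.25 ± 0.17. Among 5 Y-linked genes the median was -0.01 (adjusted p = 0.830), with ZFY at 0.17 ± 0.12, TSPY at 0.09 ± 0.12 and DDX3Y at -0.06 ± 0.15. Among 18 X-linked genes it was 0.03 (adjusted p = 0.145; -0.02 with median centring). Without replicate 2 it was 0.15 (adjusted p = 0.00688) and without replicate 3 it was 0.18 (adjusted p = 0.000515). ATRX was at 0.44 ± 0.14 (mean over its 5 probes 0.033), UBE2A at 0.38 ± 0.17 and XIST at -0.02 ± 0.12. Reference genes (13) had a median of -0.10 (adjusted p = 0.0685, but 0.0370 without replicate 4 and 0.0103 to 0.0418 in 4 other settings), with RPL15 at -0.26 ± 0.11 (mean over its 3 probes -0.082) and ACTB at -0.18 ± 0.26, the latter at -1.64 on replicate 3 and at 0.17 to 0.48 on the others. Median and test differed in sign for the fatty acid oxidation, p53 and Y-linked lists, mean and median for the cumulus, p53 and Y-linked lists, and mean and test for the cumulus and fatty acid oxidation lists.

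Arrays were compared with each other across probes, which are not independent replicates. Ratios of 10 over 16 months correlated negatively between arrays of opposite dye orientation, with a mean r of -0.21 (SD 0.08, 4 pairs), and positively between arrays of the same orientation, at 0.32 for replicates 1 and 2 and 0.12 for replicates 3 and 4. In the same fit, 4 probes passed the adjusted threshold for dye and 4930 (13.6%) had an unadjusted p under 0.05. The dye count was 606 with median centring.

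Some named genes were above background on only some arrays, given here as the number at 10 and at 16 months. These were VCAN (1 and 1), HAND1 (2 and 2), PAG20 and CD74 (2 and 3), CATSPER3, CPT1B and PRM1 (2 and 4), and CPT1A and TSPY (3 and 1). ZFY (3 and 2), BTG4, ID3 and RLBP1 (3 and 4), IFIT5 (4 and 2), and LOC781710, KIF27 and DDX3Y (4 and 3) were the others beside USP18. Without replicate 4, ASCL2, COL4A1, BTG4, PTPRC, TET3, LONP1, SREBF2, RPS3A, TJP3, ATRX, UBE2A, IFNT, IGF2R and ACTB passed as well, with adjusted p from 0.0128 to 0.0489. IFNT was at -0.64 in that fit, and without replicate 3 TKDP1 passed (1.22, adjusted p = 0.0170). Without replicate 3 the values were 0.11 for ASCL2, -0.19 for COL4A1, 0.16 for PTPRC, 0.12 for LONP1, 0.083 for SREBF2, 0.32 for TJP3 and 0.14 for UBE2A. They were 0.71 for IFNT, -0.086 for IGF2R and 0.27 for ACTB. Of 79 named genes, 47 moved by over 1.5 times or changed sign on leaving out some array, and 11 changed sign.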

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

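The tests of spot noise, of dye orientation and of the control spots on replicate 3, the counts of splits for single probes, and the comparison of list medians between splits, were chosen after the result was seen. The other tests were set down before their values were seen, although the correlations between arrays and the list medians per array were already known.

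In 114 sets of 4 array values, 10 had an array far from the other 3 by Dixon's criterion. For independent values chance gives about 1 in 20, or 5.70. These sets share arrays, hold the dye effect and include many genes picked for their values, so 5.70 is no exact reference. Of the 10, 6 were on replicate 3. On that array the log2 ratio of 10 over 16 months was 1.90 for EPAS1 (0.22 to 0.48 elsewhere), 1.82 for SENP2 (0.35 to 0.38) and 1.12 for UBE2A (0.03 to 0.20). It was -1.94 for IFNT (0.60 to 0.76 elsewhere) and -1.64 for ACTB (0.17 to 0.48). The SD of the log2 ratio over probes was 0.47 there and 0.30 to 0.32 elsewhere. On replicate 4, TKDP1 was at 2.27, against 0.00042 to 0.30 on the others. On replicate 2, NOTCH2 was at -0.033, against 0.52 to 0.57. On replicate 1, CPT1A was at 0.42, against 0.06 to 0.10, and the correlation with the authors' value table was 0.991, against 0.978 to 0.980.

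The array of replicate 3 stood apart from the others. Independent noise of single spots is argued against as the whole cause: 2 probes of 1 gene had a covariance of 0.0550 in the Cy5 over Cy3 ratio there (95% bootstrap interval 0.0428 to 0.0682, 1651 genes), above 0.0201 to 0.0279 on the other arrays, while their correlation of 0.210 lay within the 0.158 to 0.234 of the others. The SD between probes of 1 gene was also larger there, at 0.457 against 0.299 to 0.329, so spot noise as part of the cause remains open. A dye orientation recorded the wrong way round could not be settled: turning that array's sign gave 0.764 times as many probes at an unadjusted p under 0.05, but 2.33 times as many with a 1.5-fold difference as well (135 against 58), and since the turned fit sets replicate 4 alone against 3 arrays, neither count bears on the orientation. With that sign turned the oxidative phosphorylation median was -0.0021 in place of -0.15 and the ribosomal one -0.084 in place of -0.13. None of the 3 lists called as recorded was called then. The 2 lists called in their place were cell cycle and X-linked genes, with medians of -0.085 and 0.13. The turned fit also gives replicate 4 more weight, so its medians do not tell orientation and weight apart. Orientation leaves the SD of a ratio as it is, so it bears on direction only. Labelling or hybridisation could not be settled from the E1A control spots, whose mean log2 Cy5 over Cy3 ratio was 0.51 there and 0.05 to 0.42 elsewhere. The test asked for a gap wider than the SD over probes, 1.40 to 1.48, so it could hardly be met. Raw bright corner medians were lower on replicate 3 (Cy5 1628.5 against 2811.5 to 3325, Cy3 1753.5 against 4150.5 to 5982). Raw E1A medians were higher there in Cy5 (10283.5 against 6865.5 to 7223) but not in Cy3 (5196 against 5123.5 to 6732.5). DCP control spots were not apart in Cy5 (5840.5 against 5371.5 to 5939) but were highest there in Cy3 (8747 against 7138 to 8003.5). A difference between sires or embryo pools remains open and untested, since the labels tie no array to a bull.

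Oxidative phosphorylation and ribosomal protein genes had lower values at 10 months with camera at the preset correlation, but with an estimated correlation the adjusted p was 0.619 for both. That correlation was estimated at 0.158 and 0.183 after age and dye were fitted, against the preset 0.01. The genes of each list thus varied together more than the preset test assumes, though only 2 residual degrees of freedom underlie the estimates. A remaining trend with intensity is argued against as the whole cause: 0 of 10000 random lists matched on intensity had a median as low as the oxidative phosphorylation list, a share entered as 1e-04, the smallest they can give, and a share of 0.004 had one as low as the ribosomal list. The random lists did lean the same way, with medians of -0.03 and -0.05. They were drawn from all genes, the members of the tested lists included, and did not keep the way genes of a list vary together. Their shares therefore bear on intensity only. Whether genes varying together between arrays, whatever the sire age, gave the low medians could not be settled: 1 of the other 6 splits gave an oxidative phosphorylation median as large in size (0.20 against 0.15), but it sets replicate 3 alone against 3 arrays, and the 2 other splits of 2 against 2 gave -0.098 and 0.02. For ribosomal proteins the real split gave -0.126. The splits with replicate 2 alone and with replicate 3 alone gave medians as large in size, 0.187 and -0.128. The 2 other splits of 2 against 2 gave 0.029 and 0.086. An effect of sire age remains open as well.

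Cy5 over Cy3 ratios correlated positively between arrays of opposite dye orientation, with a mean r of 0.21, so what they shared followed the dye and not the sire age. Dye bias of single probes or spot background is consistent with this, since 4348 probes above background on no array gave a mean r of 0.214 as well (SD 0.05, 4 pairs). Among tested probes the mean r was 0.28 (SD 0.05) in the 9082 dimmest and 0.17 (SD 0.20) in the 9081 brightest, a difference within the spread of the pairs. No biological explanation was tested.

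The 4 arrays allow 7 splits of their signs, too few for a share under 0.05. The real split gave 0 probes past the adjusted threshold (limma, 1439 at an unadjusted p under 0.05), and the highest other gave 1496. That split has replicate 3 alone on 1 side, where the fit meets it exactly and its wider ratios do not enter the error, so it points to a structure of the samples only in that this array stands apart. The 2 other splits of 2 arrays against 2 gave 0 each (1307 and 1557 at an unadjusted p under 0.05). Every split gives at least 0, so the count of 7 of 7 was fixed in advance and tests nothing. For probes past an unadjusted p of 0.05 and a 1.5-fold difference, the real split gave 58 and the highest other 1182, and 5 of the 7 gave as many. For gene lists at the preset correlation the real split gave 3 and the highest other 5, and 3 of the 7 gave as many.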

How the results depend on the processing

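Tests chosen after the data were seen were spot means, set-aside spots kept, both together, plain background subtraction, and leaving out arrays for the dye count and the correlation between arrays; the other alternatives were planned. The cause was not tested where a value moved, unless stated.

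With limma, the adjusted count was 0 under every other setting run, with 472 to 1764 probes at an unadjusted p under 0.05, but 0 to 1858 on leaving out an array: 0 without replicate 1 or 2, 6 without replicate 3 and 1858 without replicate 4. In each such fit 1 array alone stands for its dye orientation and is assumed to vary like the others, and without replicate 4 that array is replicate 3. The 58 probes past an unadjusted p of 0.05 and a 1.5-fold difference became 38 with no background correction, 1439 with no fold minimum, 7 with spot means, 30 with set-aside spots kept, 2 with both, and 130 to 1287 without 1 array (130, 177, 136 and 1287 without replicates 1 to 4). The count was 31 with channels taken separately and no replicate block, that is, with the pairing of channels on an array ignored. The stricter filter gave 39 higher and 5 lower.

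The 3 lists called became 5 with no filter on dim probes, 2 to 6 without 1 array (6 without replicate 2), and 0 with camera at an estimated correlation, with directional fry and with mixed fry. In those 3 tests, in that order, the adjusted p was 0.619, 0.530 and 0.934 for oxidative phosphorylation (median -0.15), 0.619, 0.290 and 0.934 for translation (-0.075), and 0.619, 0.530 and 0.934 for ribosomal proteins (-0.13). Translation was at -0.10 (adjusted p = 0.0625) with median centring, -0.057 (adjusted p = 0.0792) with spot means and set-aside spots kept, and -0.13 to -0.068 without 1 array. Its call was lost without replicates 1, 3 and 4. Ribosomal proteins were at -0.19 to -0.069 without 1 array, the last without replicate 2 (adjusted p = 0.0556). Oxidative phosphorylation kept its direction and its call at the preset correlation, at -0.21 to -0.081 without 1 array, the last without replicate 3.

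The mean correlation of -0.21 between opposite orientations was -0.33 with median centring and -0.31 with spot means. The 4 probes past the adjusted threshold for dye became 606 with median centring, 0 with spot means (limma, age and dye in 1 model, 4930 at an unadjusted p under 0.05 in the main setting) and 0 to 3116 without 1 array (744 without replicate 3, 3116 without replicate 4). Of 1404 values of single genes, 1361 moved by less than the SD over arrays, an SD that includes the dye effect. A further 15 moved by more, and 28 passed the adjusted test (27 without replicate 4, 1 without replicate 3). Of the 1404 values, 29 changed sign, 0 of them among 230 values of the 13 genes named for having the same sign on all 4 arrays. Since those genes were chosen by sign, leaving out an array could not change it, so that 0 is no measure of stability. Of 549 values of lists not called, 514 moved by less than that SD, 21 by more, 14 passed, and 37 changed sign. With all 4 arrays, those that passed were sperm and testis (median centring, adjusted p = 0.0215; no filter, 0.0170), growth factors (stricter filter, 0.0452) and reference genes (4 settings, 0.0103 to 0.0418). Aquantile left every ratio as it was by construction. The fitted ratio of a probe was also unchanged with no dye term, another probe filter, array weights, another variance model or separate channels. Single-gene values under those settings therefore could not move, and they count among the 1361. A scanner-processed signal was not run. Dim signal over background limited 7294 probes, which were tested only with no filter.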

Other observations

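The genes named here were chosen after their values were seen, and none passed the adjusted test (limma, smallest adjusted p 0.957). Probes of TRIB1, a pseudokinase that steers protein degradation, GCH1, the entry enzyme of tetrahydrobiopterin synthesis, and POLE3, a histone-fold subunit of DNA polymerase epsilon, had log2 ratios of 10 over 16 months of 0.65 ± 0.12, 0.65 ± 0.13 and 0.60 ± 0.12 (SE), positive on 4 of 4 arrays. They are not the brightest probe of their gene, so the naming rule left them out, and the brightest probes of TRIB1, GCH1 and POLE3 were at 0.20 ± 0.15, 0.13 ± 0.19 and -0.10 ± 0.14.

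MGC148328 had the largest log2 ratio of all probes, at 1.86 ± 0.69, with 0.77, 5.81, -0.49 and 1.34 on replicates 1 to 4. LOC781841 followed the same order of arrays, with 0.52, 4.71, -0.44 and 1.31. Both values rested on replicate 2. LOC786530 was at 0.97 ± 0.40, with 2.94 on replicate 4 and 0.0060 to 0.86 on the others.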
